A study of Mus musculus with 9 samples.

How the data were processed

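RNA was measured in primary peritubular myoid cells from C57BL/6J mouse testis, the contractile cells that surround the seminiferous tubules. Per the labels' protocols, dishes of cells were held in a water bath at 42 °C for 30 min, returned to the incubator at 37 °C and collected 1 h or 6 h later, beside untreated cells. The 9 libraries fall into 3 groups of 3: control, 1 h after heat and 6 h after heat. The labels number the replicates but do not say whether they came from separate animals or cultures, so every p-value here measures the spread between these libraries, which may be technical. Per the labels' protocols, total RNA was extracted with TRNzol and libraries were made by BGI's standard protocol. The kit, its strand setting and the read length are not given in the sources used here.

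The deposited table holds 1 row per gene. Per the file headers its values per library are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), written to 2 decimals. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mm10 genome, without saying which step each tool did. The same table holds the authors' log2 fold changes between group means and the authors' p-values and q-values for the 3 comparisons, made with DEGseq per the file headers. Of 20717 genes listed, 17559 had values in the libraries and 3158 had none. FPKM values are shares of a library, so a rise in some transcripts lowers the values of the others, and reads that match several transcripts are divided among them by a method the table does not record. Coordinates are those of the table, on mm10, counted from 1.

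Depth was estimated from the smallest values, because 1 read gives a fixed FPKM for a transcript of known length. Over transcripts of 400 to 1200 bp, with a length offset of 35 bp, the estimate was 19100000 to 20000000 reads per library, the highest 1.05 times the lowest. In each library 84.7% to 87.7% of the low values lay within 0.2 of a whole read, where 40% would by chance. On simulated data the estimate was off by at most 0.079%. Whole reads were not recovered for all genes, so no count test was run.

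Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 11460 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend, no replicate block and all 9 libraries in 1 fit with 3 group means, which leaves 6 residual degrees of freedom. It was two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. The design was written for RPKM values or counts. The table holds FPKM, to which the same log-scale test applies. Gene lists fixed before the data were examined, 34 in all with 600 different symbols, were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over lists and comparisons, and again with the correlation estimated from the data. Camera sets the change of a list against that of the other genes, so a list is called higher or lower relative to them. A list needed at least 3 tested genes, which left 33. Of the symbols, 4 were found under another name through NCBI gene identifiers.

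The genes named were set by a rule fixed before the data were examined: the 8 called genes with the largest change in each direction that had a mean of at least 5 FPKM in the higher group and no overlap between groups, up to 4 called members of each list, the 3 highest markers of each other cell type, and 18 genes chosen in advance, of which 1 is not reported. Genes named outside that rule are said to be so. The tests were checked on simulated data with the real genes' means and spreads and 200 changed genes among 11460. For the 1 h comparison, 46.3% of genes changed by a log2 of 1, 88.1% of those changed by 2 and 100% of those changed by 4 were called, with 3 false calls. The shares were 49.3%, 89.6% and 98.5% with 14 false calls for 6 h against control, and 46.3%, 95.5% and 95.5% with 11 false calls for 6 h against 1 h. The simulation gave the groups equal spread for each gene, and 200 changed genes ease the adjusted threshold. In the real data fewer genes were called and the median SD was 0.147 at 1 h and 0.282 at 6 h. The shares called there may therefore be lower, above all at 6 h. The list test called both comparisons in which a list had been raised, out of 99 tests, and none of the others. The simulated genes were drawn independently, so this check does not cover lists whose members vary together. In the real data the estimated correlation between members was 0.97 for mitotic genes.

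The labels give the groups the same replicate numbers, and whether these pair the libraries was checked by correlating each library's deviations from its group mean. Control and 1 h libraries of the same number correlated at 0.19, 0.15 and 0.26, all above 0.1, so for that comparison the numbers were taken to pair the libraries. The control and 6 h libraries gave -0.18, 0.041 and 0.014 and the 1 h and 6 h libraries -0.27, -0.10 and -0.35, so there they were not. Of the 9 libraries, 3 correlated best with a library of their own number among the other groups. That is no more than arbitrary numbering would give, so the pairing is uncertain and the main test was kept without a block. A fit with the replicate number as a block called 15 genes at 1 h against control, all higher, 0 at 6 h against control and 23 at 6 h against 1 h, all lower.

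The alternatives were other scalings (median of ratios, quantile), pseudocounts of 0.1 and 0.5, no filter or a minimum of 5 FPKM, variance without trend or robust, only the 2 groups compared, a replicate block, a minimum of 2-fold, a threshold of 0.01, an estimated correlation for lists, and leaving out each library in turn. A count model planned for a table with counts was not run, since the table holds FPKM. After the data were seen, 3 kinds were added: leaving out control 3 and 6 h replicate 2 together, a block within the control and 1 h libraries, and weights per library. Recurring sequences were sought in GENCODE vM21 transcripts with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with Matplotlib 3.10.9.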

Results

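The transcriptome of mouse testicular peritubular myoid cells was measured without heat and at 1 h and 6 h after 30 min at 42 °C, in 3 libraries per group. The series asks how heat stress affects these cells. Each library held an estimated 19100000 to 20000000 reads, so depth differed by at most 1.05 times. Pearson correlations of log2 values across genes ranged from 0.931 to 0.983 for pairs of libraries within a group and from 0.915 to 0.985 for pairs from different groups. The median SD between replicates was 0.237 log2 units in the control group, 0.147 at 1 h and 0.282 at 6 h.

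The libraries carried transcripts of other testicular cell types at levels that differed between replicates. Insl3 and Cyp11a1, products of Leydig cells, were present in every library, at 181 to 1607 FPKM and 288 to 820 FPKM. Of 11 fixed Leydig markers 7 passed the filter. Cyp17a1, Hsd17b3, Lhcgr and Hsd3b6 reached at most 0.11, 0.12, 0.27 and 0.94 FPKM (named after their values were seen). Clu and Cldn11, both abundant in Sertoli cells, stood at 2700 and 237 FPKM in control 3, while the other 8 libraries held at most 437 FPKM of Clu and 8.23 FPKM of Cldn11. Lyz2, a lysozyme of macrophages, ranged from 132 to 178 FPKM in 1 h replicates 2 and 3 and 6 h replicates 1 and 2 and from 19.2 to 60.02 FPKM in the other 5 libraries. Acta2, Myh11, Des and Cnn1, contractile genes of myoid cells, passed the test in no comparison.

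**Figure D1:**
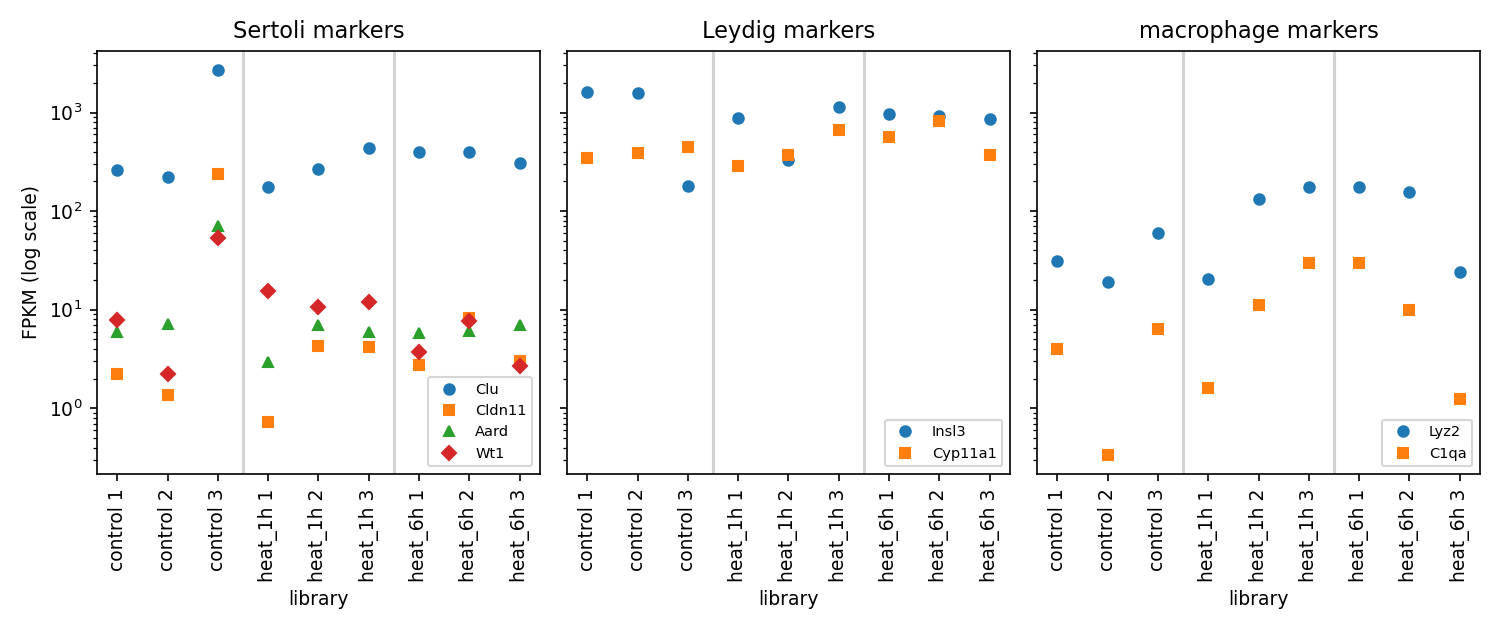
FPKM on a log axis of Sertoli, Leydig and macrophage marker genes in each of the 9 libraries, 1 point per gene and library, with grey lines between the groups. Cldn11, Aard, Wt1 and C1qa were chosen after their values were seen. Clu and Cldn11 stand at 2700 and 237 FPKM in control 3, above the other 8 libraries, and Lyz2 is at 132 FPKM or more in 4 libraries of the heated groups.

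The first comparison asked which transcripts differed from control 1 h after heat. In total 18 genes were higher and 0 lower (limma, adjusted p below 0.05, 11460 genes tested), and at an unadjusted p below 0.05 there were 316 higher and 922 lower, where 573 are expected by chance. Chaperones led the list. Hspa1a, an inducible HSP70 (NCBI gene 193740, chromosome 17, 34969359 to 34972156, minus strand), stood at 9.81 ± 2.71 FPKM in control and 1511 ± 283 at 1 h (SD, n = 3). Its log2 change was 7.14 (SE 0.26) with a limma adjusted p of 3.7e-06. Hspa1b, its near-identical neighbour, changed by 6.47 with an adjusted p of 1.2e-05, and the division of reads between the 2 copies is uncertain. Dnajb1, an HSP40 co-chaperone (chromosome 8, 83608175 to 83612653), went from 23.2 ± 4.1 to 546 ± 110 FPKM, a log2 change of 4.49. Bag3, a co-chaperone of HSP70, changed by 2.87, from 64.2 ± 4.7 FPKM in control to 479 ± 64 at 1 h.

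Of 27 chaperones tested, 6 were higher over all genes tested and 14 when adjusted over the list alone, and 0 were lower by either count. The other members called over all genes were Dnajb4 and Dnaja1, further HSP40 family members, with log2 changes of 2.13 and 2.07 (Dnaja1 was named after its values were seen). Hsph1, Hspb1 and Hsp90aa1 had log2 changes of 4.03, 2.92 and 1.84 with adjusted p of 0.13, 0.28 and 0.26 over all genes, in a fit whose spread includes the 6 h libraries, which differed widely for these genes. With only the control and 1 h libraries in the fit, 47 genes were higher and 2 lower, and all 18 were among them, with Hsph1, Hspb1 and Hsp90aa1 in addition. The chaperone list as a whole was higher at the preset correlation (camera adjusted p = 2.1e-34), which was lost with an estimated correlation (adjusted p = 0.18 with an estimated correlation).

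The other 12 calls included transcription factors and stress-response genes. Atf3, a stress-induced transcription factor, went from 6.37 ± 3.78 to 135 ± 23 FPKM, a log2 change of 4.37 with a limma adjusted p of 0.004. Chac1, which degrades glutathione and is a target of ATF4, changed by 3.0, and with Atf3 it gave 2 called members of 17 on the integrated stress response list, or 4 adjusted over the list alone. Herpud1, a component of endoplasmic reticulum protein degradation, changed by 1.54, the 1 call among 18 endoplasmic reticulum chaperones, with 2 adjusted over the list alone. Under the replicate block its adjusted p was 0.051. Arc and Egr4, genes known for activity-dependent induction, changed by 5.23 and 3.77, Tnfsf18, a TNF family ligand, by 3.35, and Tnfaip6, a hyaluronan-binding protein, by 3.16. Of 23 alternatives 11 ended the call of Tnfaip6, 10 that of Herpud1, 9 that of Chac1 and 1 that of Egr4, and 0 that of Hspa1a, Atf3, Arc or Tnfsf18. Of 24 immediate early genes 0 passed over all genes and 16 were higher adjusted over the list alone, and the list's median log2 change was 1.49. Fos had a log2 change of 1.90 with an adjusted p of 0.39.

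**Figure D2:**
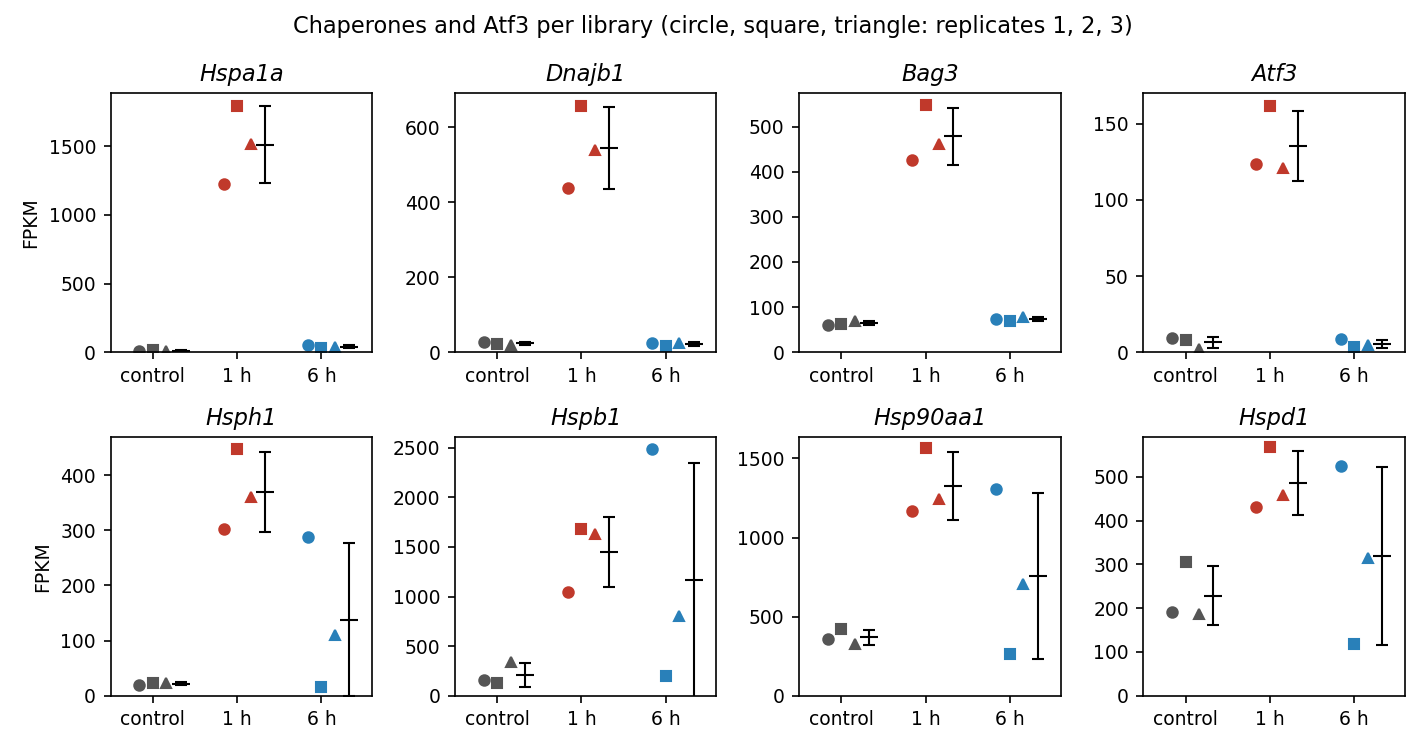
FPKM of 8 genes in control cells and at 1 h and 6 h after heat, Hspd1 being chosen after its values were seen, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean with its SD (n = 3), ended at 0 where the SD exceeds the mean. Hspa1a reached 1511 FPKM on average at 1 h, and Hsph1 at 6 h stood at 289, 15.9 and 110 FPKM in the 3 replicates.

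Lists of other functions were also tested at 1 h. With the preset correlation 18 of 33 lists were higher relative to the other genes and 0 lower, and with an estimated correlation 0 were called. Correlation between members does not by itself account for that loss. Matrix proteases had an estimated correlation of -0.011, below the preset 0.01, yet their camera p went from 2.5e-05 to 0.0042 (adjusted p = 0.18). Of the 10 ways of dividing the same 6 libraries, 3 gave 18 lists or more, the labelled one included, and the highest gave 19. Among the 18 were extracellular matrix genes (median log2 change 0.32, 0 of 28 called, adjusted p = 0.21 with an estimated correlation), markers of fibroblasts and testicular stroma (median 0.50, 0 of 12 called, adjusted p = 0.21 with an estimated correlation) and macrophage markers (median 0.95, 0 of 11 called, adjusted p = 0.39 with an estimated correlation). Cytosolic ribosomal proteins were higher relative to the other genes (median 0.039 beside -0.168 over all genes, 0 of 30 called, adjusted p = 0.81 with an estimated correlation). This turned lower with quantile normalization and without control 3. Of 17 secreted factors of myoid cells 3 were higher adjusted over the list alone and 0 over all genes. Gdnf, a growth factor for spermatogonia, lay below the filter. Csf1 had a log2 change of 0.30 with an adjusted p of 0.68.

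Most genes lay slightly lower at 1 h. The median log2 change over all genes was -0.168, and median-of-ratios scaling brought it to -0.014. Genes whose 3 libraries did not overlap with the controls numbered 514 higher and 2458 lower, 25.9% of those tested where chance gives 10%. After that scaling they numbered 1044 higher and 801 lower, and after quantile normalization 868 higher and 1161 lower. The number of called genes at 1 h depended on single libraries. Without control 1, 2 or 3 there were 11, 10 and 11 genes higher, without 1 h replicates 1, 2 or 3 there were 10, 8 and 8, and without 6 h replicates 1 and 2 there were 30 and 45. The genes lower were 2 without control 2, 1 without control 3 and 8 without 6 h replicate 2. Without control 3 and 6 h replicate 2 together 22 genes were higher and 1 lower, and 14 of the 18 were among these 23.

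The second comparison asked which transcripts differed from control 6 h after heat. No gene passed (0 higher, 0 lower, limma, smallest adjusted p 0.52), with 145 higher and 384 lower at an unadjusted p below 0.05, where 573 are expected by chance. Hspa1a stood at 38.9 ± 11.2 FPKM and had a log2 change of 1.88 with an adjusted p of 0.52. Hspa1a and Hspa1b were the 2 chaperones of 27 that were higher adjusted over the list alone. Hsph1 was at 289, 15.9 and 110 FPKM in replicates 1, 2 and 3, Hsp90aa1 at 1307, 264 and 703 and Hspb1 at 2484, 202 and 804, so the spread between replicates exceeded the difference from control for these genes. Bbc3 and Gadd45a, targets of p53, were lower adjusted over their list of 18 alone, Bbc3 being named after its values were seen. Lists called at the preset correlation numbered 6 higher and 4 lower, and 0 with an estimated correlation. Without 6 h replicate 1 there were 25 genes higher, led by Park2, a ubiquitin ligase gene, at 309 and 201 FPKM in replicates 2 and 3 and 0.16 in replicate 1 (named after its values were seen), and leaving out any other library gave 0. Of these 25, 22 belonged to a set of 24 genes that stood more than 2 times above every other library, in FPKM + 1, in replicates 2 and 3 alone.

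The third comparison set 6 h against 1 h and tested the change between the times directly. In total 32 genes were lower and 0 higher (limma), and with quantile normalization 48 were lower and 7 higher. At an unadjusted p below 0.05 the balance was opposite, with 968 higher and 366 lower, where 573 are expected by chance. Hspa1a, Hspa1b and Dnajb1 had log2 changes of -5.27, -4.94 and -4.58, and Atf3, Arc and Egr4 -4.43, -4.31 and -3.95. Of the 18 genes called at 1 h, 17 were lower at 6 h than at 1 h and 1, Tnfaip6, was not called (adjusted p 0.059). Both comparisons use the same 1 h libraries, so the second is not independent of the first. Their log2 changes correlated at -0.661 across genes with a covariance of -0.102, beside simulated means for unchanged groups of -0.499 and -0.047 with equal spread and -0.307 and -0.026 with the SD of each group, in both cases for independent libraries. At 6 h the median share of the 1 h log2 change that was left was 2.0%, between -26.3% and 26.3%, and 9 of the 18 genes were above control. The spread in the fit includes the 6 h libraries, so genes that varied there were less likely to be among the 18. Hsph1, Hspb1 and Hsp90aa1, not called, had log2 changes at 6 h of 1.87, 1.98 and 0.77, beside 4.03, 2.92 and 1.84 at 1 h. Hspa5 and Fos, also not called, had -0.094 and -0.18 at 6 h, beside 1.06 and 1.90 at 1 h. Another 15 genes were called at 6 h against 1 h and not at 1 h against control. Noct, which encodes the circadian-regulated nocturnin, changed by -3.31, Klf6 by -2.54, Jun by -2.23 and Gadd45a by -1.86. Klf6 and Jun lost the call under the replicate block (adjusted p 0.054 and 0.057), and of 22 alternatives 8 ended the call of Klf6, 9 that of Jun, 6 that of Noct and 1 that of Gadd45a.

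By list, 8 of 27 chaperones were lower adjusted over the list alone and 6 over all genes, and of 24 immediate early genes 17 and 2. Of 18 p53 targets 7 and 1 were lower. Lists called at the preset correlation numbered 3 higher and 11 lower, and 0 with an estimated correlation. Without 1 h replicates 1, 2 or 3 the genes lower numbered 18, 11 and 8, without 6 h replicate 3 they numbered 18, and without 6 h replicate 1 there were 65 lower and 39 higher.

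**Figure D3:**
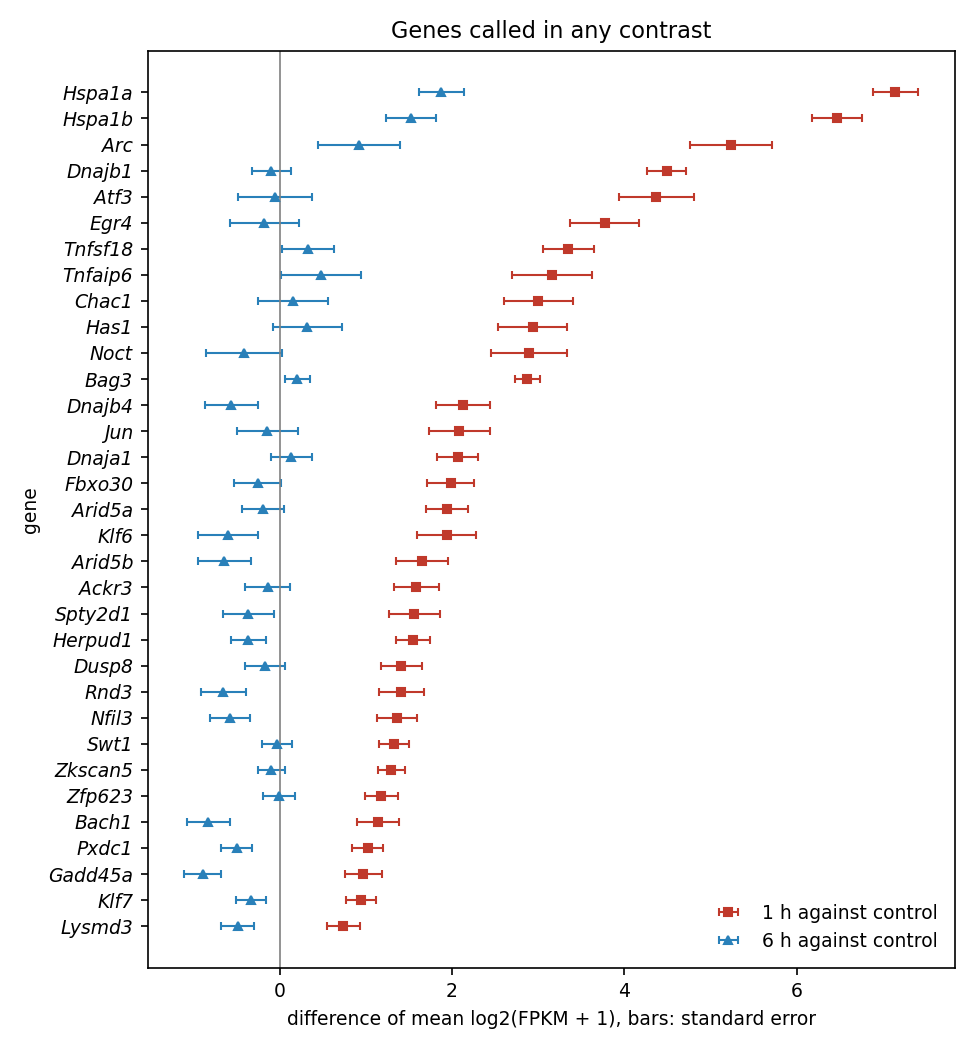
Difference of mean log2(FPKM + 1) from control at 1 h (squares) and 6 h (triangles) for the 33 genes called in any comparison, with bars for the standard error. At 1 h the values run from 0.74 for Lysmd3 (named after its values were seen) to 7.14 for Hspa1a, and at 6 h Hspa1a is at 1.88.

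No gene was shared between the calls at 1 h and at 6 h against control, as 6 h had 0 calls, and simulated unchanged groups gave a mean overlap of 0.05. The log2 changes of both comparisons correlated across genes at 0.472, and simulated unchanged groups, which share the control libraries and have equal spread, gave 0.501. The covariance was 0.062 beside a simulated mean of 0.047 (0.042 to 0.052 in 100 simulations). With the SD of each group, a simulation added after the data were seen, the means were 0.561 and 0.054 (covariance 0.049 to 0.062). Both simulations draw libraries independently and leave out any pairing of control and 1 h libraries, so they are not exact values for no change. The authors' deposited table lists 1260 genes at 1 h, 1040 at 6 h and 722 for 6 h against 1 h with a q-value of at most 0.001 and at least 2-fold. Of those tested here, 55.0%, 17.9% and 57.1% had no overlap between the libraries of the 2 groups, beside 25.9%, 7.2% and 20.2% of all genes tested. A choice by fold change between the same groups raises this share by itself.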

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

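All tests of explanations in this part were chosen after the results were seen. The 32 genes lower at 6 h than at 1 h were marked because the response at 1 h and at 6 h differed by a direct test. Dividing the 6 libraries in the other 9 ways gave at most 0 genes for this comparison, against 32 as labelled, and at most 0 for 1 h against control, against 18. For 6 h against control the labelled division gave 0 and the highest other 0. As many genes as with the labels were given by 1 of the 10 divisions for 6 h against 1 h, 1 for 1 h against control and 10 for 6 h against control, the labelled one included. With 10 divisions the share cannot go below 0.1, so this test is too coarse for the threshold. For 1 h against control, 4 divisions part all 3 numbered pairs, and of these the highest other also gave 0. Lists behave differently. As labelled, 18, 10 and 14 lists were called at the preset correlation for 1 h, 6 h and 6 h against 1 h, and the highest other divisions gave 19, 16 and 20, with 3, 8 and 6 of the 10 divisions reaching as many.

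The 6 h libraries disagreed on some chaperones: of 12 above all controls in replicates 1 and 3, replicate 2 had 5 below all controls, 5 above them and 2 among them. Hsph1 was 15.9 FPKM in replicate 2, below its controls (18.6 to 23.1), and 289 and 110 FPKM in replicates 1 and 3. Hspa1a and Hspa1b stood at least 1.76 times above the highest control in replicate 2. Their controls alone ranged from 6.92 to 12.3 FPKM and from 14.0 to 29.8 FPKM, and the division of reads between the 2 copies is uncertain. With 5 chaperones below all controls, an unheated library in that place can therefore not be excluded. A mixture of unheated cells into a library like the other 2 was argued against because 4 chaperones kept a smaller share of their excess over control than Hspa1a and Hspa1b, by more than 2 SE on each side (Hspa1a 49.2%, Hsph1 -3.1%). A different course of recovery in that culture, or a different heat dose, stays open and was not tested.

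Of 14 fixed Sertoli markers with values, 11 had their highest level in control 3, where 1.56 would by chance, led by Clu (2700 FPKM) and Cldn11 (237 FPKM). The 11 include Fshr and Amh at 0.09 and 0.26 FPKM, levels too low to rank libraries. The chance value treats the markers as independent, which markers of the same cell type are not. Markers of other types highest there included Alas2 of red blood cells (7.08 FPKM, at most 0.14 elsewhere), Star of Leydig cells (211 FPKM) and Mrc1 of macrophages (1.87 FPKM). Other members of these lists were not. Hba-a1 of red blood cells was at 0 FPKM there, and Insl3 of Leydig cells had its lowest level there (181 FPKM). Lyz2 of macrophages stood at 60.02 FPKM there and reached 178 FPKM elsewhere. The median log2 difference of control 3 from controls 1 and 2 was -0.14 for Leydig and 0.64 for macrophage markers. An equal rise of the other cell types, as a lower share of the main type alone would give, was argued against by 2 values. The Sertoli markers exceeded the Leydig markers by 2.64 in median log2 difference from controls 1 and 2, and all 9 endothelial markers were lower (-1.73 to -0.66). A lower share of the main type through added Sertoli cells was not tested, since no contractile gene was used. Sertoli cells among the cells of control 3 may account for its Sertoli markers but cannot be told apart from other sources. Gata4, Inhbb and Krt18 were not highest there and Rhox5 stood at 1.64 FPKM (Cldn11, Krt18, Rhox5, Fshr, Amh, Alas2, Hba-a1, Star and Mrc1 were named after their values were seen). No biological explanation was tested.

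A set of 24 genes on 14 chromosomes stood more than 2 times above every other library, in FPKM + 1, in 6 h replicates 2 and 3 together, and the next of the 36 pairs of libraries had 9 such genes. Park2, a ubiquitin ligase, was at 309 and 201 FPKM there and at most 3.51 FPKM elsewhere, and the group test did not call it because replicate 1 stood with the controls. A 25-base sequence chosen on 12 of the genes lay in the transcripts of 83.3% of the other 12 and in 3.4% of other tested genes, which is consistent with reads of a repeated sequence, whose family was not tested, being assigned to these genes, and in 100 random sets of 12 genes a shared sequence reached at most 5. Against a simple form of this, the 388 other genes with the sequence had a median log2 difference of 0.060, beside 0.029 for genes without it. Whether the reads came from RNA of the repeat or from genomic DNA was not tested, and these genes were chosen after their values were seen.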

How the results depend on the processing

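The alternatives that left out control 3 and 6 h replicate 2 together, blocked the control and 1 h libraries, or weighted libraries were chosen after the data were seen. Of 561 values of called named genes under alternatives, 493 kept their call, 68 lost it and 0 changed sign. Of 935 values of called lists (estimated correlation included), 840 kept the call, 87 lost it and 8 turned. Of values not called at first, 23 of named genes and 81 of lists gained a call, most often endothelial markers at 6 h (11 of 21 alternatives) and mitotic genes at 6 h against 1 h (9 of 21). No count test was run, since the table holds no counts. A robust variance and a minimum of 2-fold left the counts of calls as they were. At 19100000 to 20000000 reads depth was alike in all libraries and limits low genes in each. The smaller counts at adjusted p 0.01 follow from the threshold; for the other values below the cause was not tested.

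With the replicate block there were 15 genes higher at 1 h, 0 at 6 h and 23 lower at 6 h against 1 h. Genes called at 1 h and in the opposite direction at 6 h against 1 h numbered 13. The block ended the calls of Herpud1 at 1 h and of Klf6 and Jun at 6 h against 1 h, added 4 list calls (glycolysis, endothelial markers and contractile genes at 6 h, mitotic genes at 6 h against 1 h) and changed no other call of a named gene or list.

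Genes higher at 1 h (18) numbered 31 with quantile normalization, 9 without a filter, 47 with only the 2 groups compared, 8 at adjusted p 0.01, 46 with the block in control and 1 h libraries, 97 with library weights and 325 with REML weights. Genes lower at 1 h (0) numbered 1 without a filter, 1 with a minimum of 5 FPKM, 2 with only the 2 groups, 1 without control 3 and 6 h replicate 2 together, 4 with that block, 97 with weights and 1015 with REML weights. Genes higher at 6 h (0) numbered 1 with weights, and the overlap with 1 h was then 1. Genes higher at 6 h against 1 h (0) numbered 7 with quantile normalization, 1 with a pseudocount of 0.1 or of 0.5, 1 without a filter, 3 with a minimum of 5 FPKM, 3 without a variance trend, 5 without the 2 doubted libraries, 1249 with weights and 152 with REML weights. Genes lower at 6 h against 1 h (32) numbered 21 without a filter, 17 at adjusted p 0.01, 408 with weights and 111 with REML weights. Genes called at 1 h and in the opposite direction at 6 h against 1 h were also counted (17). They numbered 26 with median-of-ratios scaling, 29 with quantile normalization, 9 without a filter, 8 at adjusted p 0.01, 173 with weights and 210 with REML weights. A return to the control level was not tested. With an estimated correlation 0 lists were called in each comparison.

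Leaving out 1 library at a time gave 8 to 45 genes higher and 0 to 8 lower at 1 h, and 0 to 25 higher at 6 h. For 6 h against 1 h there were 0 to 39 higher and 8 to 65 lower. Genes called at 1 h and in the opposite direction at 6 h against 1 h numbered 7 to 29.

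No named gene changed sign in a comparison in which it was called. The log2 changes that did, each of a gene not called in that comparison, follow. With median-of-ratios scaling these were at 1 h Insl3 0.013, and at 6 h Cirbp 0.036, and at 6 h against 1 h Esam -0.016. With quantile normalization these were at 1 h Cyp11a1 -0.013, and at 6 h Cirbp 0.090. Without control 3 and 6 h replicate 2 together these were at 1 h Clu 0.17, Inhbb -0.063, Cd14 -0.22, S100a4 -0.026, Csf1 -0.0064, and at 6 h Insl3 -0.80, Akr1cl -0.48, Clu 0.53, Inhbb -0.23, Hspa2 0.12, S100a4 -0.11, Des 0.53, Cnn1 0.77, Cirbp 0.018, and at 6 h against 1 h Inhbb -0.17, Lyz2 -0.24, S100a4 -0.081, Myh11 0.15. With library weights these were at 1 h Inhbb -0.027, Cd14 -0.15, and at 6 h Insl3 -0.55, Akr1cl -0.054, Clu 0.019, Inhbb -0.48, Zbtb16 -0.13, Col1a1 -0.11, Ly6a -0.19, Des 0.024, Cnn1 0.44, and at 6 h against 1 h Inhbb -0.45, Lyz2 -1.26, Cd68 -0.56, Cdh5 -0.053, Acta2 0.17. Without 1 library at a time, log2 changes at 1 h ranged as Insl3 -1.21 to 0.38, Cyp11a1 -0.27 to 0.34, Cd14 -0.25 to 0.46, Hspa2 -0.11 to 0.42, Clu -1.63 to 0.17, Inhbb -0.063 to 0.24, S100a4 -0.19 to 0.66, Csf1 -0.0064 to 0.57. Without 1 library at a time, log2 changes at 6 h ranged as Dnajb1 -0.22 to 0.11, Hspa5 -0.29 to 0.024, Fos -0.88 to 0.48, Cirbp -0.24 to 0.20, Gata4 -0.030 to 0.22, Cd14 -0.56 to 0.076, Cdh5 -0.44 to 0.039, Rbm3 -0.37 to 0.14, Insl3 -0.80 to 0.78, Clu -1.21 to 0.59, Hspa2 -0.38 to 0.16, Cnn1 -0.98 to 0.24, Akr1cl -0.32 to 0.66, Inhbb -0.083 to 0.65, Des -1.04 to 0.11, Csf1 -0.58 to 0.0083. Without 1 library at a time, log2 changes at 6 h against 1 h ranged as Lyz2 -0.78 to 1.08, Cd68 -0.23 to 0.75, Emcn -0.20 to 0.80, S100a4 -0.081 to 0.80, Cnn1 -0.29 to 0.80, Insl3 -0.13 to 0.77, Ddx4 -0.66 to 0.32, Esam -0.51 to 0.64, Myh11 -0.83 to 0.31, Akr1cl -0.65 to 0.32, Cdh5 -0.047 to 0.29, Des -0.26 to 0.90, Inhbb -0.17 to 0.56, Col1a1 -0.50 to 0.19, Ly6a -1.10 to 0.063.

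Some list tests turned direction, given here by their camera adjusted p. With quantile normalization these were at 1 h cytosolic ribosomal proteins 0.405. Without control 3 and 6 h replicate 2 together these were at 1 h cytosolic ribosomal proteins 0.131, and at 6 h cytosolic ribosomal proteins 0.102, mitochondrial respiratory chain subunits 0.0018, p53 targets 0.760, proteasome 26S subunits 0.550. Without 1 library at a time, adjusted p at 1 h ranged as DNA replication genes 2.2e-05 to 0.979, mitotic genes 0.00081 to 0.999, cytosolic ribosomal proteins 1.6e-06 to 0.461, cholesterol synthesis 0.020 to 0.992. Without 1 library at a time, adjusted p at 6 h ranged as immediate early genes 0.00092 to 0.999, Sertoli 0.018 to 0.925, mitotic genes 6.7e-11 to 0.971. Without 1 library at a time, adjusted p at 6 h against 1 h ranged as cytosolic ribosomal proteins 2.8e-05 to 0.776, macrophage / leukocyte 0.0085 to 0.504.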

Other observations

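With only the control and 1 h libraries in the fit, the further genes higher at 1 h included Dnaja4, an HSP40 family member, with a log2 change of 3.84, and Zfand2a, a known heat-induced proteasome regulator, with 1.49. Maff and Klf6, both on the immediate early list, had 1.94 each. The 2 genes lower were Sema4b (-0.92) and Dok1 (-1.14). Genes other than Klf6 in this paragraph were chosen after their values were seen.

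The 18 genes called at 1 h and the fixed chaperones, 39 genes together, made up 1.23% of summed FPKM in control on average, 3.86% at 1 h and 1.71% at 6 h. The 6 h replicates 1, 2 and 3 held 2.43%, 1.13% and 1.58%. At 1 h this share, counted in summed FPKM, would lower the other genes by a log2 of -0.039, beside the median change of -0.168 over all genes. The share of fragments, to which FPKM is scaled, also depends on transcript length and was not computed. How far these genes account for the median change was therefore not tested.

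Weights per library were tried after the data were seen, and their outcome depended on how they were estimated. A gene-by-gene estimate gave 97 genes higher and 97 lower at 1 h, and an estimate by REML, which stopped before it converged, gave 325 and 1015. The weights ran from 0.261 for 6 h replicate 2 to 3.09 for 6 h replicate 3 by the first. Over the other 9 divisions of the control and 1 h libraries the first gave at most 4 genes, against 194 as labelled. With 10 divisions in all, this test too is too coarse for the threshold and does not settle the weighted count.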
